A study of Homo sapiens with 11 samples.

How the data were processed

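Total RNA of 3T3-L1 cells, a mouse fibroblast line that can be turned into fat cells, was sequenced in 11 libraries. The titles place 2 libraries at 0 h and 3 each at 24 h under the names DM, EtOH and DHA. DHA is the usual abbreviation of docosahexaenoic acid, a polyunsaturated fatty acid, although the labels do not spell it out. The labels name the organism as human, while the gene identifiers of the tables are mouse identifiers and the line is of mouse origin, so mouse was used throughout. Per the labels, cells were differentiated after 2 days at confluence with a historical cocktail, a control cocktail lacking DHA or a cocktail with DHA. The components and the matching of DM and EtOH to these cocktails are not given, and each group is named here by its title. RNA was extracted with RNeasy columns, and random-primed libraries were read from both ends on a HiSeq4000 instrument.

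Per the submitters' processing notes, the authors used FastQC, Trimmomatic, STAR 2.5.1b, HTSeq 0.9.1, Cuffdiff 2.2.1 and kallisto 0.43.1 with genome build GRCm38.p5. The strand setting and the annotation release are not given in the sources used here. The authors deposited raw HTSeq counts per gene and library as whole numbers without normalization. They also deposited kallisto estimated counts per RefSeq transcript and library. The third deposited table holds Cuffdiff FPKM, with 1 value per group, so that it carries no spread between libraries.

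The HTSeq table held 51826 genes. Those with too few reads were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14633. TMM factors were computed, and 1 quasi-likelihood model with a mean per group was fitted to all 11 libraries. The common biological coefficient of variation was 4.86%. Each of the 6 pairs of groups was compared with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Genes past that threshold are called changed, higher or lower. Levels are given in CPM, computed with the TMM factors, as mean ± SD over the libraries of a group, and log2 fold changes with ± SE. The p-values measure the spread between these samples, since the labels do not say whether replicates are separate cultures. Replicate numbers were not treated as pairs, since the labels give them no meaning.

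A set of 27 gene lists from textbook knowledge, covering pathways and cell types, was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes. Adjustment was by Benjamini-Hochberg over the 23 lists with at least 5 tested genes. Camera was repeated with the correlation estimated from the data, beside fry. Lists of macrophage, endothelial, epithelial and skeletal muscle markers were included to look for other cell types. The lists of fatty acid receptors and of endothelial and epithelial markers had 0 tested genes and that of muscle had 4, so these were not tested as lists. Members were counted as higher or lower after adjustment over all genes, and again adjusted over the list alone. Some lists share genes, such as Angptl4 among PPAR and glucocorticoid targets, so their results are not independent. Members also found in other lists were 8 of 24 adipocyte markers, 6 of 18 triglyceride genes and 7 of 20 glucocorticoid targets.

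Genes are named by a rule. In DHA against EtOH, DM against EtOH, DHA against DM and EtOH against 0 h, these are the 8 largest rises and 8 largest falls among changed genes. Eligible genes had a mean of at least 5 CPM over the 11 libraries, a symbol that is not a predicted-gene name, and every library of the higher group above every library of the lower. In the other 2 comparisons, 5 and 5 were taken. Up to 4 members of each described list with the smallest p were added, and Ffar4, Cebpa, Cebpb, Cebpd, Pparg, Fabp4, Adipoq, Plin2, Angptl4 and Ctcf were always included. The comparisons, tests, lists, this rule and the alternatives named below, except those said to be added later, were fixed before the data were examined. Gene positions are the loci of the Cuffdiff table on GRCm38, counted from 1, and are given only where the locus holds a single gene.

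Total counts per library ranged from 18412500 to 26381429. A floor of 3 counts per library, the number a count of 0 allows, lay between 0.114 and 0.163 CPM. Where every library of a group was at 0, the fold is given as a lower bound against the mean floor of that group's libraries. Where a group held 1 to 3 counts in all, the ratio of pooled CPM is given with its exact Clopper-Pearson interval of 95%. Floors and these intervals cover counting error only.

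The scripts were tested on simulated data drawn with the depth and spread of these counts, with 50 genes changed at each fold. All other genes had the same mean in every group. The share of genes changed was smaller than the share called in the data, and recovery depends on it. The percentages that follow therefore need not hold for the data. For DHA against EtOH, 54% of genes changed 1.25-fold were recovered, 78% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, and 4.82% of the calls were false. For EtOH against 0 h, with 2 libraries at 0 h, the shares were 36%, 60%, 80% and 96%, with 6.85% false calls.

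Alternatives were RLE and upper-quartile normalization, no filter on low counts, a minimum mean of 5 CPM, limma-voom, DESeq2 1.42.0, a fit of the 2 compared groups alone, a replicate term, and leaving out each library in turn. Thinning each library to the smallest total, transcripts from kallisto and group FPKM were added after the data had been seen. The human reference annotation at hand was not used. Figures were drawn with matplotlib 3.10.9.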

Results

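RNA of 3T3-L1 cells was measured by sequencing before differentiation (0 h, 2 libraries) and 24 h into it under the titles EtOH, DHA and DM (3 libraries each). Total gene counts were 19101027 and 22610447 at 0 h, 20666713, 24865204 and 18412500 in EtOH, 25832917, 26381429 and 21214462 in DHA, and 20500445, 18603760 and 18824341 in DM, in the order of replicates. Of 51826 genes in the table, 28102 had at least 1 count, 23724 were at 0 in every library, and 14633 were tested. Among the genes at 0 were 5368 that code for protein, and all 37 mitochondrial genes, so nothing can be said about transcripts of the mitochondrial genome. Ffar4, which encodes a cell-surface receptor for long-chain fatty acids, had 0 counts in all 11 libraries, and the deposited FPKM was 0 as well. Ffar1, Ffar3 and Gpr119, other lipid receptors, had 0 counts too, and Ffar2 had 1. Adipoq, which encodes the fat-cell hormone adiponectin, had 0 to 2 counts per library and was not tested.

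In a principal component analysis of log2 CPM, the first component held 63.1% of the variance and set DM apart from every other library. The second held 21.3% and set 0 h apart from EtOH and DHA. EtOH lay between −26.0 and −24.2 on the first component and DHA between −17.8 and −17.5. Ribosomal RNA counts made up 0.903% and 1.19% at 0 h, 1.31%, 1.57% and 1.34% in EtOH, 1.93%, 1.77% and 0.773% in DHA, and 1.94%, 2.04% and 1.64% in DM. DHA replicate 3 had the lowest share of all. A chi-square per gene between replicates, ribosomal RNA genes included, is near 1 under counting error alone. It was 16.2 and 14.7 between DHA replicate 3 and the other DHA libraries, and between 2.71 and 6.46 for all other pairs.

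**Figure D1:**
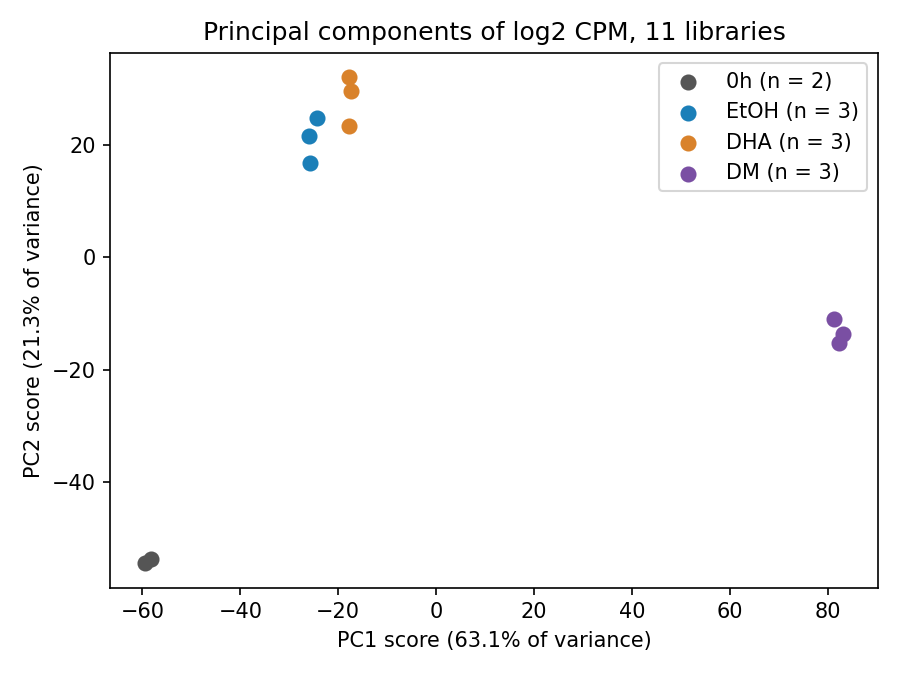
Scores of the 11 libraries on the first (63.1% of the variance) and second (21.3%) principal component of log2 CPM, 1 point per library, coloured by group. DM lies between 81.2 and 83.0 on the first component, and EtOH and DHA lie next to each other.

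Cells under DHA were compared with cells under EtOH to see which genes differed between these 2 titles at the same time of differentiation. Most genes of fatty acid use and lipid storage were higher with DHA, and most genes of cholesterol synthesis, fatty acid synthesis and desaturation, and the interferon response were lower. Among target genes of the PPAR receptors for fatty acid use, 19 of 21 were higher and 2 were not called, and of genes for cholesterol synthesis and uptake 22 of 24 were lower and 2 were not called. All 21 interferon-stimulated genes tested were lower. The differences were small for most genes: 1129 were changed, 664 of them higher and 465 lower, and 88 of these differed at least 2-fold. Camera called 14 of the 23 tested lists, and 7 of them with an estimated correlation too.

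Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781575), which encodes a secreted inhibitor of lipoprotein lipase, rose most among the genes eligible for naming. Its level was 521 ± 37.4 CPM with DHA and 71.1 ± 3.998 CPM with EtOH (SD, n = 3 each), a log2 fold change of 2.87 ± 0.06 (adjusted p = 2.21e-16, edgeR). Cpt1a (chromosome 19, 3323301 to 3385732), whose product brings fatty acids into mitochondria, rose from 145 ± 2.44 to 330 ± 3.67 CPM (SD, n = 3 each). Ucp2, a carrier of the inner mitochondrial membrane, rose by 1.18 ± 0.05 on the log2 scale, and Pdk4, a kinase that turns off pyruvate dehydrogenase, by 0.94 ± 0.05. The PPAR target list was called higher by camera (adjusted p = 2.07e-113), and with an estimated correlation too (adjusted p = 0.000598). Adjusted over the list alone, 19 of 21 were again higher. Acsbg1, an acyl-CoA synthetase, rose by 1.15 ± 0.11.

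Most adipocyte markers were higher too, some of them from low levels. Fabp4 (chromosome 3, 10204088 to 10208576), the fatty acid carrier of fat cells, was at 34.7 ± 6.20 CPM with DHA and 8.14 ± 0.32 CPM with EtOH (SD, n = 3 each), with a log2 fold change of 2.09 ± 0.11 (adjusted p = 5.58e-10, edgeR). Plin1, which coats the lipid droplets of fat cells, rose by 4.47 ± 0.30, Cd36, a fatty acid uptake receptor, by 3.64 ± 0.25 and Cidec, which enlarges lipid droplets, by 3.45 ± 0.24. Plin1, Cd36 and Cidec were under 1 CPM with EtOH. Of 17 adipocyte markers, 12 were higher, 1 was lower and 4 were not called (13 higher and 1 lower adjusted over the list alone), and the list was called higher (adjusted p = 2.75e-34, and 0.00224 with an estimated correlation). Plin2 (chromosome 4, 86648386 to 86670060), a droplet coat protein found in many cell types, rose from 190 ± 9.86 to 326 ± 21.9 CPM (SD, n = 3 each). Of 15 genes for triglycerides and lipid droplets, 8 were higher and 7 not called, and 8 were higher adjusted over the list alone (adjusted p = 2.23e-17, and 0.00368 with an estimated correlation). Fitm2, needed to form droplets, rose by 0.75 ± 0.06 and Pnpla2, the adipose triglyceride lipase, by 0.57 ± 0.05.

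Transcription factors of fat-cell differentiation moved less. Cebpa, which acts late in differentiation, rose from 10.4 ± 1.29 to 17.2 ± 1.65 CPM (SD, n = 3 each; log2 fold change 0.72 ± 0.10, adjusted p = 0.000153, edgeR). Pparg, the central regulator of fat-cell differentiation, was called higher by 0.30 ± 0.08 (adjusted p = 0.0195). That call was lost without EtOH replicate 1 (0.32, adjusted p = 0.0552), EtOH replicate 3 (0.25, adjusted p = 0.101), DHA replicate 1 (0.24, adjusted p = 0.129) or DHA replicate 3 (0.26, adjusted p = 0.0848), and when these 2 groups were fitted alone (adjusted p = 0.0521). Stat5a, a factor that acts with them, rose by 0.25 ± 0.05. The early factors Cebpb and Cebpd were not called, at log2 fold changes of 0.11 ± 0.07 and −0.04 ± 0.05 (adjusted p = 0.379 and 0.699). The list of adipogenic transcription factors was called higher (adjusted p = 0.00700) but not with an estimated correlation (adjusted p = 0.153). Of its 18 genes 5 were higher and 13 not called (6 higher and 1 lower adjusted over the list alone). The 5 became 3 without EtOH replicate 1 and 2 without EtOH replicate 3, DHA replicate 1 or DHA replicate 3.

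**Figure D2:**
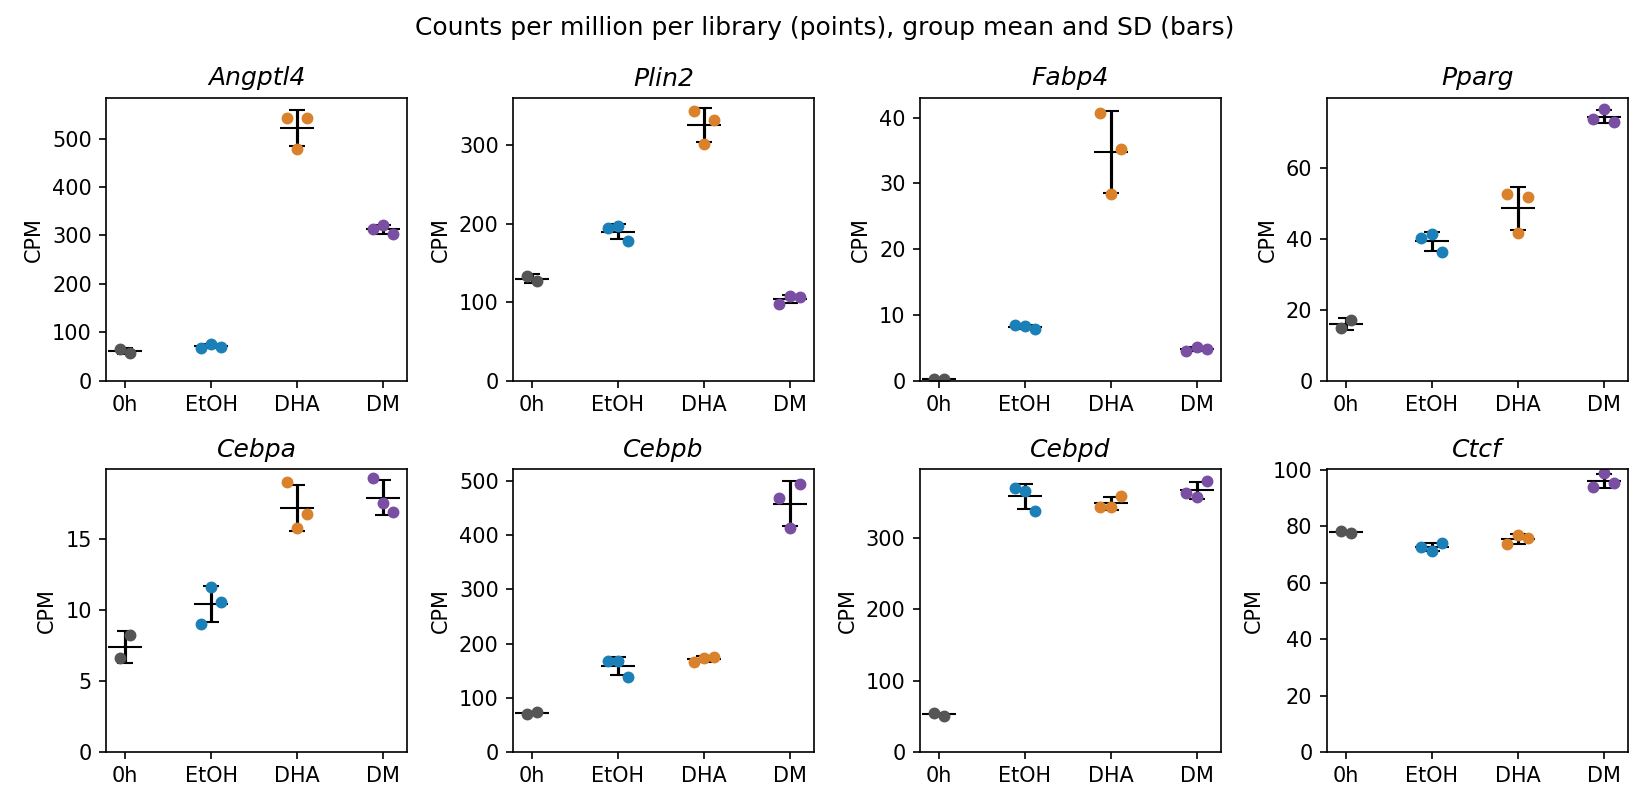
Level in CPM of Angptl4, Plin2, Fabp4, Pparg, Cebpa, Cebpb, Cebpd and Ctcf in each library (points), with the mean and SD of each group (lines and bars), for 0 h, EtOH, DHA and DM. Angptl4 averaged 71.1 CPM with EtOH, 521 CPM with DHA and 312 CPM with DM, and Cebpd was alike in the 3 groups at 24 h.

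Most cholesterol and desaturase genes were lower with DHA. Fdft1, squalene synthase, fell by 0.999 ± 0.07 on the log2 scale, Sqle, squalene epoxidase, by 0.93 ± 0.05 and Insig1, which holds back the sterol-sensing factor SREBP, by 0.79 ± 0.05. Adjusted over the list alone, 23 of the 24 cholesterol genes were lower, and the list was called lower (adjusted p = 1.91e-99, and 0.00159 with an estimated correlation). The desaturase Scd2 fell from 1096 ± 32.5 to 540 ± 11.9 CPM (SD, n = 3 each). Scd1 fell by 0.51 ± 0.06 on the log2 scale, and Fads2 and Fads1, desaturases in the making of polyunsaturated fatty acids, by 0.86 ± 0.05 and 0.49 ± 0.04. Of 16 genes of fatty acid synthesis and desaturation, 10 were lower and 1 higher (12 and 2 adjusted over the list alone; adjusted p = 3.96e-26, and 0.00277 with an estimated correlation). LXR target genes were called lower (adjusted p = 2.85e-05, and 0.00873 with an estimated correlation), with 3 of 10 lower and 1 higher in both counts. Among them Abca1, which exports cholesterol, fell by 0.74 ± 0.08 and Mylip, a ubiquitin ligase, by 0.69 ± 0.06. The 1 higher gene in these lists was 0 without EtOH replicate 1, EtOH replicate 3, DHA replicate 1 or DHA replicate 3.

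Interferon genes made up the 8 largest falls eligible for naming. These were Mx2, Zbp1, Ifit3b, Tgtp1, Ifit3, Ifit1, Ifi44 and Usp18, most of them antiviral effectors induced by interferon, with log2 fold changes between −1.73 ± 0.18 for Mx2 and −1.38 ± 0.17 for Usp18. Ifit1 was at 14.3 ± 2.12 CPM with DHA and 43.5 ± 14.99 CPM with EtOH (SD, n = 3 each; adjusted p = 9.24e-06, edgeR). Zbp1, a sensor of nucleic acids, fell by 1.71 ± 0.17 on the log2 scale. Ifit3 and Ifit3b are near-identical copies, and Tgtp1 shares its locus with other genes, so reads can be divided between copies. Stat2 and Irf9, subunits of the factor that interferon activates, fell by 0.78 ± 0.08 and 0.69 ± 0.07, Irf7 by 0.98 ± 0.11 and Oasl2 by 1.38 ± 0.14. The list was called lower (adjusted p = 4.03e-52, and 0.00774 with an estimated correlation), and 21 of 21 were lower adjusted over the list alone. Summed over the list, the libraries held 925, 697 and 937 CPM with EtOH, the lowest in replicate 2, and 495, 523 and 471 CPM with DHA. At 0 h they held 2365 and 2461 CPM.

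Peg10 (chromosome 6, 4747306 to 4760517), an imprinted gene derived from a retrotransposon, rose from 73.0 ± 4.78 to 318 ± 53.3 CPM (SD, n = 3 each; log2 fold change 2.12 ± 0.09, adjusted p = 1.09e-11, edgeR). Retnla, a secreted resistin-like protein, rose by 1.64 ± 0.21 at a low level of 2.39 CPM. Glycolysis genes such as Ldha, Pgam1 and Pfkl rose by 0.63 ± 0.10, 0.63 ± 0.09 and 0.59 ± 0.09, while Ndrg1, a hypoxia gene in the same list, fell by 0.51 ± 0.09. Of the 20 glycolysis genes 14 were higher and 1 lower (16 and 1 adjusted over the list alone; adjusted p = 2.3e-12, but adjusted p = 0.153 with an estimated correlation). The groups overlapped for this list: its mean log2 CPM above 0 h was 0.72, 0.42 and 0.73 in the DHA libraries and 0.29, 0.44 and 0.21 in the EtOH libraries, so that DHA replicate 2 lay below EtOH replicate 2. Ctcf, which encodes a chromatin-loop factor, was not called at 0.05 ± 0.04 (adjusted p = 0.526), and 0 of the 12 genes for CTCF, cohesin and the cAMP-activated factor EPAC were called, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 2 of these 12, limma-voom and DESeq2 called 0 after adjustment, and camera did not call the list (adjusted p = 0.794).

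Cell-cycle and respiratory lists were called higher, but not with an estimated correlation, and their counts moved with single libraries. Of 23 S-phase genes 12 were higher and 11 not called (17 and 1 adjusted over the list alone; adjusted p = 3.28e-10, and adjusted p = 0.137 with an estimated correlation), but only 6 were higher without EtOH replicate 1 or 3 (with 1 lower without EtOH replicate 3) and 7 without DHA replicate 1 or 3. Of 22 G2 and M phase genes 8 were higher (20 adjusted over the list alone; adjusted p = 7.97e-11, and adjusted p = 0.153 with an estimated correlation). There the count was 5 without EtOH replicate 1 or DHA replicate 3, 4 without DHA replicate 1 and 17 without DHA replicate 2. Top2a, a DNA topoisomerase of dividing cells, rose by 0.34 ± 0.04, and Uhrf1, which copies DNA methylation, by 0.40 ± 0.06. Of 23 respiratory chain genes 7 were higher (14 adjusted over the list alone; adjusted p = 1.3e-07, and adjusted p = 0.242 with an estimated correlation), with 3 without EtOH replicate 1 and 4 without EtOH replicate 3, DHA replicate 1 or DHA replicate 3. Etfa, which passes electrons from fatty acid oxidation to the chain, rose by 0.41 ± 0.05. DHA replicate 3, with its low ribosomal share, belongs to the group in which these lists were higher. It did not stand apart in the cell-cycle lists. Mean log2 CPM of S-phase genes above 0 h was 0.59, 0.48 and 0.60 in DHA replicates 1, 2 and 3, and that of G2 and M phase genes 2.26, 2.09 and 2.26.

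Glucocorticoid target genes were called higher (adjusted p = 0.000521, and adjusted p = 0.153 with an estimated correlation), with a mean log2 fold change of 0.16 and a median of 0.02. The call rested on Angptl4: without it the mean of the other 18 genes was 0.0047 and the list was not called (adjusted p = 0.566). Of 19 genes 2 were higher and 3 lower (3 and 3 adjusted over the list alone), and the call was lost without a filter (adjusted p = 0.713). The 2 became 1 without EtOH replicate 1, EtOH replicate 3, DHA replicate 1 or DHA replicate 3, and the 3 became 1 without EtOH replicate 1, EtOH replicate 2 or DHA replicate 2. Tsc22d3, an anti-inflammatory target of the glucocorticoid receptor, fell by 0.22 ± 0.04. Matrix and contractile genes were called higher (adjusted p = 0.0221, and adjusted p = 0.295 with an estimated correlation), a call lost without DHA replicate 1 (adjusted p = 0.0839) and without a filter (adjusted p = 0.0508). Of 21 genes, 5 were higher and 2 lower (5 and 3 adjusted over the list alone). The 5 became 3 without DHA replicate 1, and the 2 became 1 without EtOH replicate 1 or 2 or any 1 of the 3 DHA libraries. Acta2, smooth muscle actin, rose by 0.65 ± 0.09, while Dcn, the matrix proteoglycan decorin, fell by 0.33 ± 0.06. Camera did not call the lists of oxidative stress (adjusted p = 0.1199), prostaglandins (0.172), cilium and hedgehog (0.267), preadipocyte genes (0.439), stress response (0.622), macrophage markers (0.737), inflammation (0.840) or cAMP targets (0.981). The test pointed up for the last 2 lists, although the median of the inflammatory list was −0.01 and the mean of the cAMP list was −0.09. The oxidative stress list was called without EtOH replicate 1 (adjusted p = 0.0414) and without a filter (adjusted p = 0.0467).

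How many genes were changed moved with the library left out. A group is then cut to 2 libraries, so fewer calls can also follow from the smaller number. The count was 638 without DHA replicate 1 (360 higher, 278 lower) and 705 without EtOH replicate 1 (414 higher, 291 lower). It was 787 without EtOH replicate 3, where the higher genes numbered 438 and those lower by at least 2-fold 32 in place of 54. Without DHA replicate 3 it was 874, without EtOH replicate 2 it was 944, and without DHA replicate 2 it rose to 1360.

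**Figure D3:**
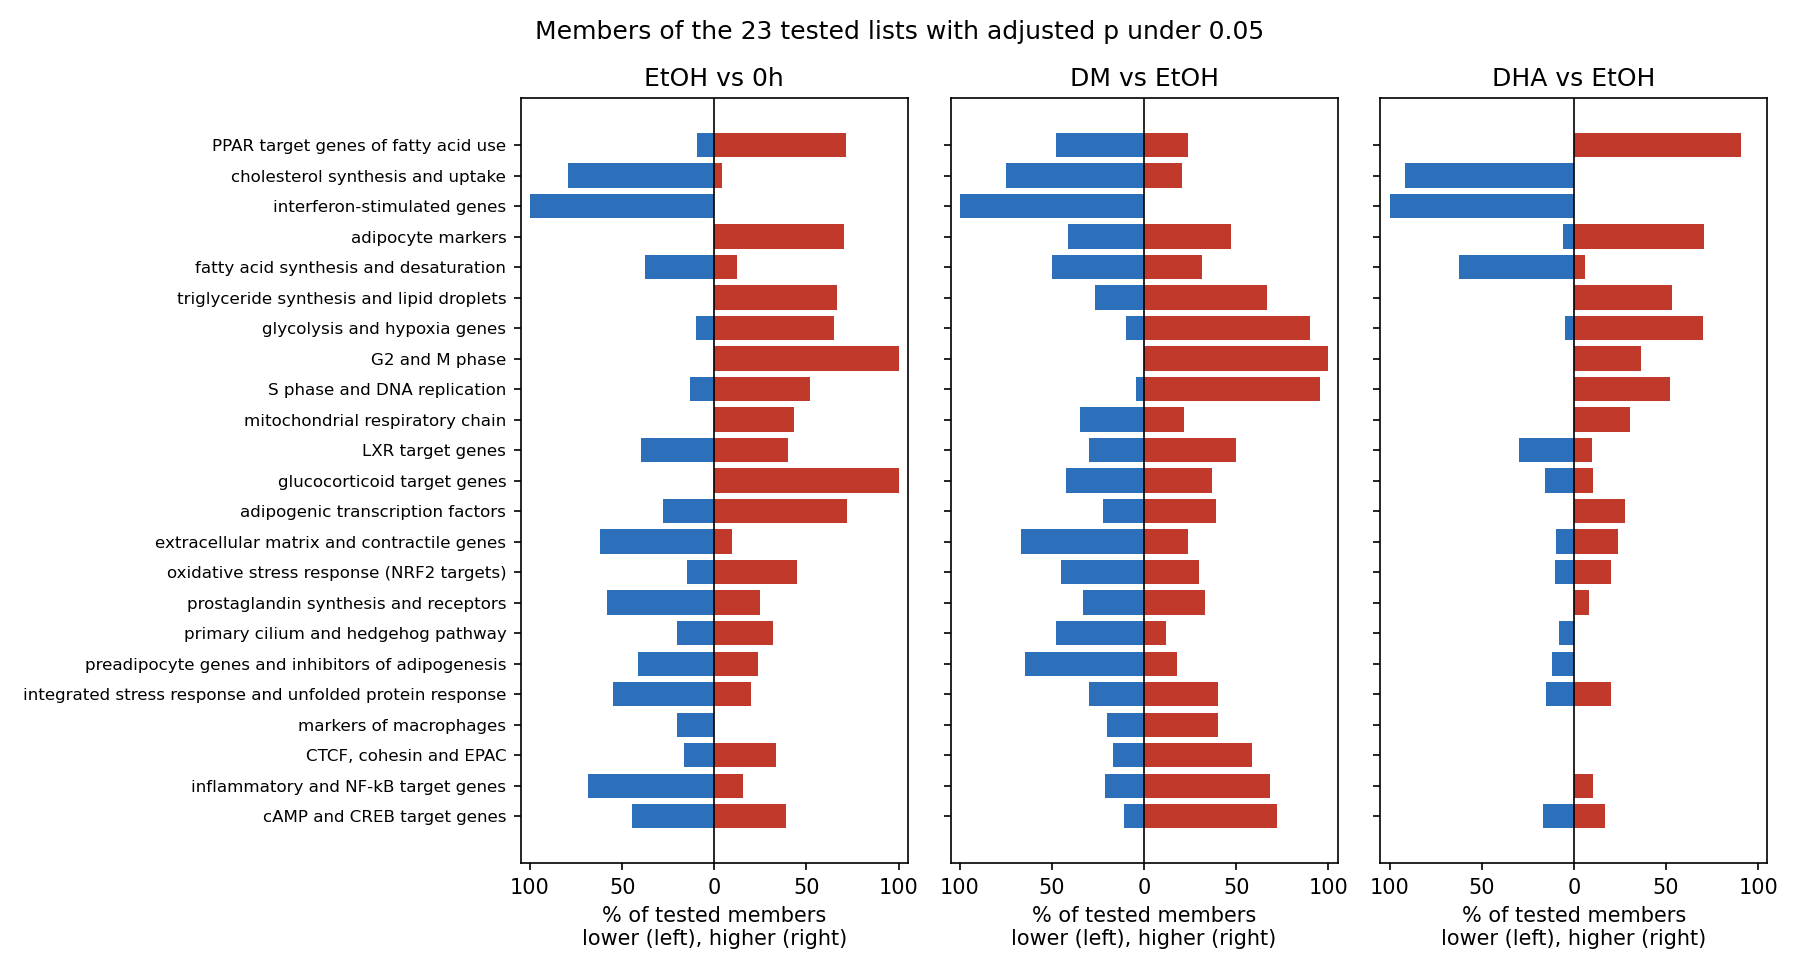
Share of each list's tested genes that were lower (left, blue) or higher (right, red) at adjusted p under 0.05, in percent, for the 23 tested lists in EtOH against 0 h, DM against EtOH and DHA against EtOH. All 21 interferon genes are lower in each comparison.

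DM was compared with EtOH to see how these other titles at 24 h differed. Most genes of the cell-division, cAMP-response and inflammatory lists were higher in DM, and most of the matrix and interferon lists were lower. Some of the largest rises were those of single acute-phase and chemokine genes. Most tested genes differed: 9583 were changed (65.5%), 4652 higher and 4931 lower, of which 1105 and 1788 differed at least 2-fold. The ribosomal RNA share was higher in the 3 DM libraries (1.64% to 2.04%) than in the 3 EtOH libraries (1.31% to 1.57%). The labels do not give the components of either medium, so no single component can be tied to a difference. Camera called 7 of the 23 lists, and 3 of them with an estimated correlation too.

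Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase protein of the serum amyloid A family, was at 1177 ± 134 CPM in DM and 2.48 ± 0.748 CPM in EtOH (SD, n = 3 each), a log2 fold change of 8.87 ± 0.12 (adjusted p = 8.54e-21, edgeR). Prg4, the joint lubricant lubricin, rose from 82.1 ± 2.63 to 3419 ± 246 CPM (SD, n = 3 each). Il13ra1, a receptor subunit for interleukins, rose by 4.85 ± 0.06, and Cxcl13, a B-cell chemokine, and Retnla rose by 5.29 ± 0.16 and 5.25 ± 0.14. Saa1 rose by 7.56 ± 0.19 from under 1 CPM, and its close copy Saa2 can share reads. Pip, a secreted glycoprotein, and Csf2rb, a cytokine receptor subunit, rose by 7.80 ± 0.20 and 5.38 ± 0.22 from under 1 CPM, and by 8.44 and 6.16 without EtOH replicate 3. Lcn2, an iron-scavenging acute-phase protein, rose by 4.39 ± 0.06, and the neutrophil chemokines Cxcl1 and Cxcl5 by 3.32 ± 0.14 and 2.31 ± 0.11. Of 19 inflammatory genes, 13 were higher and 4 lower, and as many adjusted over the list alone (adjusted p = 1.35e-06, and 0.0460 with an estimated correlation).

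Cell-division genes were higher in DM without exception in the G2 and M phase list, 22 of 22 (22 adjusted over the list alone; adjusted p = 4.64e-34, and 0.0460 with an estimated correlation). Top2a rose from 198 ± 3.82 to 1567 ± 45.8 CPM (SD, n = 3 each), Ccnb1, a mitotic cyclin, by 1.81 ± 0.06 on the log2 scale, and Cdc20 and Kif20a, which act late in mitosis, by 1.73 ± 0.05 each. Of 23 S-phase genes, 22 were higher and 1 lower in both counts, adjusted over the list alone or not (adjusted p = 1.4e-07, but adjusted p = 0.270 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 1.55 ± 0.08. Of 18 cAMP and CREB target genes, 13 were higher and 2 lower, also adjusted over the list alone (adjusted p = 7.97e-11, and 0.00355 with an estimated correlation). Pde4b and Pde4d, phosphodiesterases that break down cAMP, rose by 4.35 ± 0.06 and 1.66 ± 0.06, and Junb, a subunit of AP-1, by 3.19 ± 0.05. Glycolysis and hypoxia genes were higher in 18 of 20 and lower in 2 (the same adjusted over the list alone; adjusted p = 2.68e-06, but adjusted p = 0.526 with an estimated correlation), among them Vegfa, a vessel growth factor, at 1.92 ± 0.05 and Hk2, a hexokinase, at 1.89 ± 0.09.

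Most genes of the matrix and contractile list were lower in DM, a call lost with an estimated correlation. Ogn, the proteoglycan osteoglycin, fell from 416 ± 14.5 to 4.19 ± 1.42 CPM (SD, n = 3 each; log2 fold change −6.62 ± 0.12, adjusted p = 5.08e-19, edgeR). Postn, the matrix protein periostin, fell by 2.67 ± 0.05 on the log2 scale, Lox, a collagen cross-linking enzyme, by 2.13 ± 0.04, and the collagen genes Col1a1 and Col1a2 by 1.68 ± 0.05 and 1.39 ± 0.04. Of 21 matrix and contractile genes 14 were lower and 5 higher, also adjusted over the list alone (adjusted p = 4.98e-05, but adjusted p = 0.258 with an estimated correlation). Interferon-stimulated genes were lower in 21 of 21 (21 adjusted over the list alone; adjusted p = 8.53e-13, but adjusted p = 0.258 with an estimated correlation), and the list summed to 286, 285 and 290.1 CPM in DM. Ifit3, Ifit3b and Irf7 fell by 5.64 ± 0.40, 5.37 ± 0.38 and 3.41 ± 0.15. Other large falls were those of Igfals, which binds insulin-like growth factors, at −5.94 ± 0.21, Sult1a1, a sulfotransferase, at −5.74 ± 0.15, Aldh1a1, which makes retinoic acid, at −5.64 ± 0.15, and AU021092 at −5.20 ± 0.23. Fam180a held 526 counts in the EtOH libraries and 2 in the DM libraries, a ratio of 239 (interval 65.7 to 1975).

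Regulators of fat-cell differentiation and fat-cell markers went both ways in DM. Of 18 adipogenic transcription factors 7 were higher, 4 lower and 7 not called, with a mean log2 fold change of 0.01, and camera did not call the list (adjusted p = 0.549). Cebpb, an early regulator, rose from 158 ± 17.3 to 458 ± 41.8 CPM (SD, n = 3 each; log2 fold change 1.53 ± 0.07, adjusted p = 3.18e-13, edgeR). Ebf1, a factor of the early fat-cell lineage, fell by 0.94 ± 0.05. Pparg rose by 0.92 ± 0.08, Cebpa by 0.78 ± 0.11, Angptl4 by 2.13 ± 0.06 and Cidec by 4.57 ± 0.22. Plin2 fell by 0.87 ± 0.06, Fabp4 by 0.76 ± 0.15, Plin4, another droplet coat protein, by 1.62 ± 0.05, Pnpla2 by 1.18 ± 0.05 and Aoc3, an amine oxidase of fat cells, by 2.86 ± 0.06. Adipocyte markers were 8 higher and 7 lower of 17, PPAR targets 5 higher and 10 lower of 21, and camera called neither list (adjusted p = 0.778 and 0.786). Cebpd was not called, at 0.03 ± 0.05 (adjusted p = 0.527). Ctcf rose by 0.40 ± 0.04 (adjusted p = 8.91e-08), Rad21 and Smc3, subunits of cohesin, by 0.65 ± 0.04 and 0.52 ± 0.05, and Rapgef3, which encodes EPAC, fell by 2.24 ± 0.12. Camera did not call the list of these genes (mean log2 fold change 0.06, adjusted p = 0.267). Without a filter camera called it (mean −0.11, adjusted p = 0.0399), but the direction of that test was not kept. Ly6a, a marker of progenitor cells, rose by 2.99 ± 0.06, and Pdgfrb, a growth factor receptor of preadipocytes, fell by 2.17 ± 0.05. Of 17 preadipocyte genes 11 were lower and 3 higher, and camera did not call the list (adjusted p = 0.268). Without a filter camera called it (mean −0.66, adjusted p = 0.00559). Of the 5 macrophage markers tested, at about 10 CPM or less, 2 were higher, or 1 without DM replicate 1 or 3. Cd68 rose by 1.23 ± 0.26 and Lyz2 fell by 2.59 ± 0.40, and camera did not call the list (adjusted p = 0.864). Insig1 fell by 1.41 ± 0.05, and of 24 cholesterol genes 18 were lower and 5 higher. Camera did not call that list (adjusted p = 0.0521), but did without DM replicate 2 (adjusted p = 0.0395), without DM replicate 3 (adjusted p = 0.0392) or without a filter (adjusted p = 0.000212).

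DHA was also set against DM, the title under which cells differed most from both. Most PPAR target, matrix and interferon genes were higher with DHA, and most cell-division and cAMP-response genes were lower. Adipocyte markers went both ways. There were 9456 changed genes, 4851 higher and 4605 lower, of which 1647 and 1094 differed at least 2-fold. Camera called 10 of the 23 lists, and only that of cAMP targets with an estimated correlation too. Ribosomal RNA made up 1.93%, 1.77% and 0.773% of counts in DHA and at least 1.64% in DM.

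Ogn was at 328 ± 11.6 CPM with DHA and 4.19 ± 1.42 CPM with DM (SD, n = 3 each; log2 fold change 6.27 ± 0.12, adjusted p = 1.1e-18, edgeR). Igfals, Aldh1a1 and Sult1a1 were higher by 6.03 ± 0.21, 5.72 ± 0.15 and 5.43 ± 0.15 on the log2 scale, and Ppfibp2, a scaffold protein of cell adhesion, AU021092 and Islr, a secreted protein of stromal cells, by 5.27 ± 0.21, 5.02 ± 0.23 and 4.93 ± 0.26. Fam180a held 495 counts with DHA and 2 with DM, a ratio of 199.6 (interval 55.0 to 1652). Saa1 held 1951 counts with DM and 3 with DHA, a ratio of DM to DHA of 807 (interval 276 to 3914), and its log2 fold change went from −9.47 to −10.25 without DHA replicate 2. Other genes lower with DHA were Saa3, at a log2 fold change of −9.25 ± 0.12, Pip at −7.26 ± 0.18, Cxcl13 at −5.46 ± 0.15, Csf2rb at −5.26 ± 0.21, Il13ra1 at −4.87 ± 0.06, Prg4 at −4.75 ± 0.08 and Lcn2 at −4.26 ± 0.06.

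Fabp4 was higher with DHA than with DM by 2.85 ± 0.12, Plin2 by 1.65 ± 0.06 and Angptl4 by 0.74 ± 0.06 on the log2 scale. Plin4 and Aoc3 were higher by 2.18 ± 0.05 and 2.82 ± 0.06, and Acadl and Acaa2, enzymes of fatty acid oxidation, by 1.55 ± 0.05 and 1.64 ± 0.06. Pparg, Cebpb and Ctcf were lower, at −0.62 ± 0.07, −1.42 ± 0.07 and −0.35 ± 0.04. Cebpa was not called at −0.06 ± 0.10 (adjusted p = 0.603), nor was Cebpd at −0.07 ± 0.05 (adjusted p = 0.168), which was called under upper-quartile normalization (−0.11, adjusted p = 0.0382). PPAR target genes were higher in 18 of 21 and lower in 1, also adjusted over the list alone (adjusted p = 5.66e-08, but adjusted p = 0.248 with an estimated correlation). Adipocyte markers were higher in 9 of 17 and lower in 7 (adjusted p = 0.00269, but adjusted p = 0.441 with an estimated correlation and 0.144 without a filter).

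The 22 G2 and M phase genes were all lower with DHA than with DM (adjusted p = 1.53e-29, but adjusted p = 0.0606 with an estimated correlation), Top2a at a log2 fold change of −2.65 ± 0.05. S-phase genes were lower in 19 of 23 and higher in 1, or in 0 without DM replicate 1 (adjusted p = 4.43e-05, but adjusted p = 0.441 with an estimated correlation). Among cAMP target genes 15 of 18 were lower and 2 higher, 1 without DM replicate 2, and the call held with an estimated correlation (adjusted p = 8.69e-12 and 0.00254), with Pde4b at −4.04 ± 0.05 and Junb at −3.37 ± 0.05. Inflammatory genes were lower in 11 of 19 and higher in 4 (adjusted p = 5.37e-07, but adjusted p = 0.0554 with an estimated correlation). Matrix genes were higher in 14 of 21 and lower in 5, with 15 higher adjusted over the list alone (adjusted p = 2.83e-06, but adjusted p = 0.163 with an estimated correlation), Postn by 2.61 ± 0.05. Interferon genes were higher in 20 of 21 (adjusted p = 1.71e-05, but adjusted p = 0.441 with an estimated correlation), Irf7 by 2.43 ± 0.16. Glycolysis genes were lower in 16 of 20 and higher in 2 (adjusted p = 0.00148, but adjusted p = 0.584 with an estimated correlation), and cholesterol genes were lower in 15 of 24 and higher in 4 (adjusted p = 0.0229, but adjusted p = 0.584 with an estimated correlation). Apart from the matrix list, these counts were the same adjusted over the list alone.

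EtOH at 24 h was compared with 0 h to see what changed over the first day of differentiation without DHA in the title. All glucocorticoid target and all G2 and M phase genes tested were higher, most adipogenic transcription factors, adipocyte markers and PPAR targets were higher, and most interferon, inflammatory, matrix and cholesterol genes were lower. There were 6263 changed genes, 3044 higher and 3219 lower, of which 801 and 541 differed at least 2-fold. Camera called 13 of the 23 lists, and 3 of them with an estimated correlation too. Counts adjusted over the list alone are given where they differ. Time and the change of medium cannot be told apart here, and the 0 h group had 2 libraries, with ribosomal shares (0.903% and 1.19%) under those of EtOH.

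All 19 glucocorticoid target genes were higher, also adjusted over the list alone (adjusted p = 8.03e-70, and 0.000848 with an estimated correlation), with a median log2 fold change of 2.74, or 2.23 with genes at 0 in a group set to their lower bounds. Fkbp5, a chaperone that binds the glucocorticoid receptor, rose from 86.5 ± 7.50 (n = 2) to 1415 ± 50.3 CPM (SD, n = 3; adjusted p = 4.93e-19, edgeR), Glul, glutamine synthetase, by 4.45 ± 0.06 on the log2 scale, Tsc22d3 by 3.92 ± 0.06 and Lcn2 by 6.15 ± 0.13. By the log2 fold change of the main fit, the largest rise eligible for naming was that of Fam107a (chromosome 14, 8296274 to 8318023), a stress-responsive actin-binding protein. It went to 187 ± 13.6 CPM from 0.183 CPM. Its log2 fold change was 9.90 ± 0.17, and 10.75 without 0 h replicate 2, where that of Fam83a was larger, at 11.75. The rank is uncertain at such low levels at 0 h, and genes with 0 counts there have only a lower bound. Map7d2, a microtubule-binding protein, rose by 8.33 ± 0.22, Aldh1a7, a close relative of Aldh1a1, by 7.70 ± 0.17 and Lims2, an adhesion protein, by 7.08 ± 0.26. Ppp1r1b, a phosphatase inhibitor, and Cxcl13 had 0 counts at 0 h and rose at least 32.5-fold and 4.93-fold. Fam83a, a signalling adaptor, held 1290 counts with EtOH and 1 at 0 h, a ratio of 849.8 (interval 152 to 33589.7), with a log2 fold change of 9.41 that was 8.69 without 0 h replicate 1 and 11.75 without replicate 2. Ear1, a ribonuclease with close copies, held 571 counts and 1, a ratio of 376 (interval 67.2 to 14882), with a log2 fold change of 8.24 that was 10.60 without 0 h replicate 1 and 7.28 without replicate 2.

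**Figure D4:**
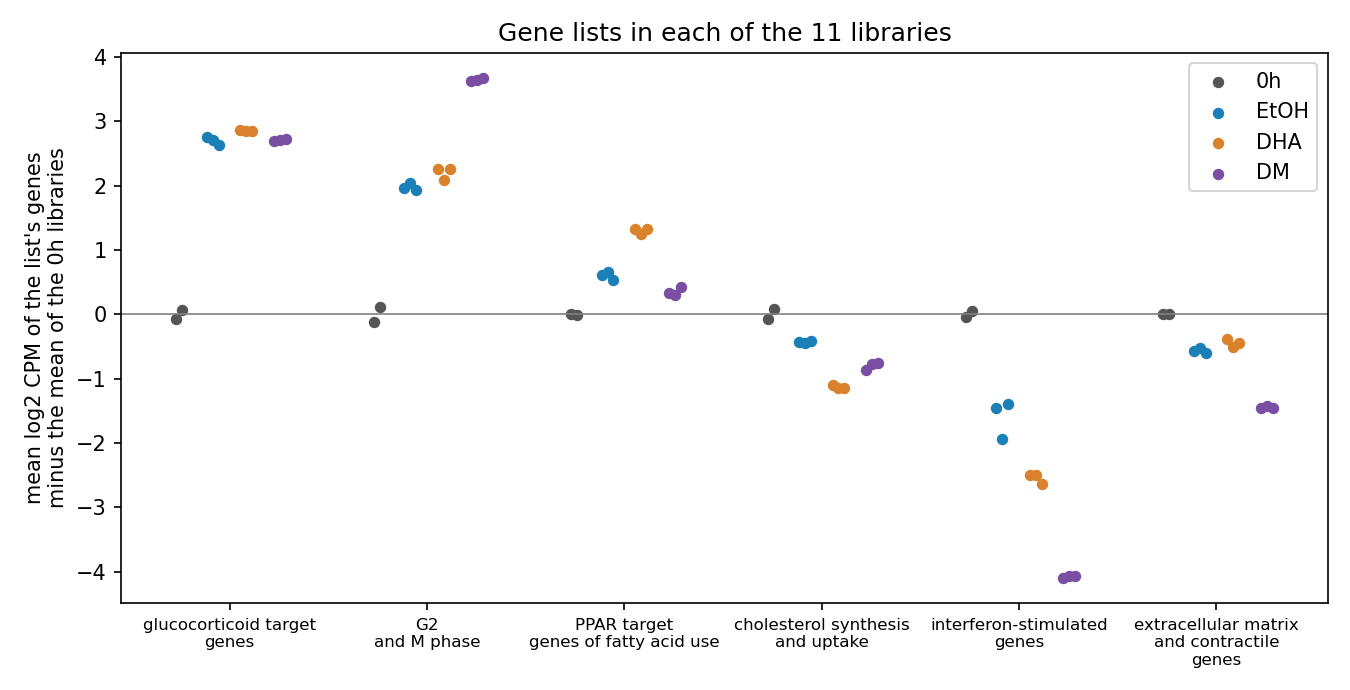
Mean log2 CPM of the genes of 6 lists in each library (points), minus the mean of the 0 h libraries, for 0 h, EtOH, DHA and DM. Glucocorticoid and G2 and M phase genes lie above 0 h in every library at 24 h, and interferon genes lie below.

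Most adipogenic transcription factors were higher in EtOH than at 0 h, and some were lower. Cebpd rose from 52.6 ± 2.57 (n = 2) to 359 ± 17.4 CPM (SD, n = 3; log2 fold change 2.77 ± 0.06, adjusted p = 2.69e-17, edgeR). Klf5, an early factor of differentiation, rose by 4.07 ± 0.10, Pparg by 1.30 ± 0.10 and Cebpb by 1.15 ± 0.08. Cebpa was called higher by 0.49 ± 0.13 (adjusted p = 0.00583), but not without 0 h replicate 1 (0.37, adjusted p = 0.0880). Adipogenic transcription factors were higher in 13 of 18 and lower in 5 (adjusted p = 5.67e-08, and 0.0405 with an estimated correlation). Fabp4 rose by 4.94 ± 0.31 from 0.265 CPM, Plin2 by 0.55 ± 0.06, Pnpla2 by 1.93 ± 0.07, Plin4 by 1.47 ± 0.06 and Pdk4 by 2.48 ± 0.07. Angptl4 was called higher by 0.22 ± 0.07 (adjusted p = 0.0146), but not without 0 h replicate 2 (0.15, adjusted p = 0.208) or EtOH replicate 2 (0.17, adjusted p = 0.0745). Adipocyte markers were higher in 12 of 17 and lower in 0, or 1 adjusted over the list alone (adjusted p = 1.58e-06, but adjusted p = 0.0826 with an estimated correlation). PPAR targets were higher in 15 of 21 and lower in 2 (adjusted p = 6.21e-06, but adjusted p = 0.218 with an estimated correlation), and triglyceride genes higher in 10 of 15 (adjusted p = 0.000905, but adjusted p = 0.122 with an estimated correlation). Ctcf was not called at −0.10 ± 0.05 (adjusted p = 0.0983).

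All 22 G2 and M phase genes were higher, also adjusted over the list alone (adjusted p = 1.43e-55, and 0.0157 with an estimated correlation), Kif20a by 2.54 ± 0.07 and Top2a by 1.81 ± 0.06. S-phase genes were higher in 12 of 23 and lower in 3, a count that was 1 without 0 h replicate 2, EtOH replicate 1 or EtOH replicate 3. Camera called that list higher (adjusted p = 0.0330), but not with an estimated correlation (adjusted p = 0.596) or without EtOH replicate 2 (adjusted p = 0.0591). Of 20 oxidative stress genes 9 were higher and 3 lower (10 and 4 adjusted over the list alone; adjusted p = 0.0330, but adjusted p = 0.501 with an estimated correlation and 0.0538 without EtOH replicate 1). Of 18 cAMP target genes 7 were higher and 8 lower, or 9 adjusted over the list alone. The test called that list higher (adjusted p = 0.0278, but adjusted p = 0.0909 with an estimated correlation and 0.599 without a filter) with a mean of 0.10 and a median of −0.34. Rgs2 and Per1, early targets of cAMP signalling, rose by 2.08 ± 0.05 and 1.56 ± 0.06.

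Interferon genes were lower in 21 of 21, also adjusted over the list alone (adjusted p = 2.53e-19, but adjusted p = 0.0826 with an estimated correlation). Isg15, the ubiquitin-like modifier, fell from 106 ± 1.83 (n = 2) to 16.9 ± 3.90 CPM (SD, n = 3; adjusted p = 1.51e-12, edgeR) and Bst2, which tethers virus particles, by 2.10 ± 0.09 on the log2 scale. Ifit3 fell by 3.09 ± 0.17. Inflammatory genes were lower in 13 of 19 and higher in 3, or 14 and 3 adjusted over the list alone (adjusted p = 0.000721, but adjusted p = 0.0826 with an estimated correlation), and Ccl2, a monocyte chemokine, fell by 2.61 ± 0.10. Matrix genes were lower in 13 of 21 and higher in 2 (adjusted p = 9.07e-07, but adjusted p = 0.0826 with an estimated correlation). Thbs1, thrombospondin, fell by 2.46 ± 0.06 and Dcn by 1.92 ± 0.06, while Lox rose by 1.44 ± 0.05. Cholesterol genes were lower in 19 of 24 and higher in 1, or 20 and 3 adjusted over the list alone (adjusted p = 8.37e-06, but adjusted p = 0.326 with an estimated correlation). The 1 became 2 without 0 h replicate 2 or EtOH replicate 3, and Sqle and Cyp51, enzymes of the pathway, fell by 0.80 ± 0.05 and 0.85 ± 0.06. Piezo2 (chromosome 18, 63010213 to 63387183), a mechanically gated channel, fell most among the genes eligible for naming, by 5.12 ± 0.15, to 1.31 ± 0.365 CPM (SD, n = 3). Gfra1, a neurotrophic factor receptor, fell by 3.92 ± 0.13, Ptprv, a phosphatase, by 3.72 ± 0.14, Ces1a, a carboxylesterase with close copies, by 3.16 ± 0.10, Cilp, a cartilage protein, by 3.14 ± 0.10, Cpa4, a carboxypeptidase, by 3.07 ± 0.15 and Sema7a, a semaphorin, by 3.05 ± 0.13.

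DHA and DM were compared with 0 h as well. With DHA, all glucocorticoid target and all G2 and M phase genes tested and most PPAR targets and adipocyte markers were higher than at 0 h, and all interferon and most cholesterol genes lower. In all, 6849 genes were changed (3349 higher, 3500 lower; 874 and 739 at least 2-fold). Fabp4 rose by 7.03 ± 0.24 on the log2 scale, Angptl4 by 3.09 ± 0.07, Cebpd by 2.73 ± 0.06, Pparg by 1.60 ± 0.10, Plin2 by 1.32 ± 0.06, Cebpb by 1.27 ± 0.08 and Cebpa by 1.21 ± 0.13, and Ctcf was not called at −0.05 ± 0.05 (adjusted p = 0.445, edgeR). Ppp1r1b rose at least 41.7-fold from 0 counts, Map7d2 by 8.58 ± 0.21, and Fam107a by 9.98 ± 0.17, or 10.82 without 0 h replicate 2. Fam83a held 1454 counts with DHA and 1 at 0 h, a ratio of 851 (interval 153 to 33652). Its log2 fold change of 9.42 was 8.69 without 0 h replicate 1 and 11.75 without replicate 2. Ear1 held 591 counts and 1, a ratio of 346 (interval 61.9 to 13692), and its log2 fold change of 8.13 was 10.49 without 0 h replicate 1 and 7.16 without replicate 2. The largest falls eligible for naming were those of Piezo2 at −5.13 ± 0.15, Ifit3 at −4.67 ± 0.20, Ifit3b at −4.19 ± 0.19, Zbp1 at −4.03 ± 0.15 and Tgtp1 at −3.99 ± 0.17. Of 23 lists camera called 17, and 8 of them with an estimated correlation too.

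The 8 lists called both ways for DHA against 0 h were led by glucocorticoid targets, with 19 of 19 higher (adjusted p = 1.6e-66, and 0.000480 with an estimated correlation). G2 and M phase genes were higher in 22 of 22 (3.26e-58 and 0.0132), PPAR targets in 19 of 21 with 1 lower (1.54e-25 and 0.0186), and adipocyte markers in 13 of 17 with 1 lower (5.67e-14 and 0.0186). Adipogenic transcription factors were higher in 13 of 18 with 5 lower (5.17e-09 and 0.0186), and triglyceride genes in 11 of 15 (6.76e-08 and 0.0249). Interferon genes were lower in 21 of 21 (6.6e-36 and 0.0224) and cholesterol genes in 21 of 24 (7.29e-26 and 0.0293). Adjusted over the list alone, 2 PPAR targets were lower and the other counts did not change. The 1 lower adipocyte marker became 2 without DHA replicate 1, and the 1 lower PPAR target became 2 without DHA replicate 2.

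With DM, all G2 and M phase genes tested and most glucocorticoid and cAMP targets were higher than at 0 h, and most matrix genes lower. In all, 9650 genes were changed (4679 higher, 4971 lower; 1547 and 2014 at least 2-fold). Cxcl13 and Ppp1r1b rose at least 198-fold and 81.8-fold from 0 counts, Prg4 by 10.89 ± 0.14, Lcn2 by 10.54 ± 0.11 and Saa3 by 10.23 ± 0.16 on the log2 scale. The largest falls eligible for naming included those of Ifit3 at −8.73 ± 0.31, Ifit3b at −7.85 ± 0.31, Ogn at −7.20 ± 0.12 and Ptprv at −7.19 ± 0.22, or −7.97 without DM replicate 3. Fam180a held 463 counts at 0 h and 2 with DM, a ratio of 0 h to DM of 319 (interval 87.7 to 2640.04). Fabp4 rose by 4.17 ± 0.35, Cebpd by 2.80 ± 0.06, Cebpb by 2.68 ± 0.09, Angptl4 by 2.36 ± 0.07, Pparg by 2.22 ± 0.10, Cebpa by 1.27 ± 0.13 and Ctcf by 0.30 ± 0.05, while Plin2 fell by 0.32 ± 0.06. Camera called 12 of 23 lists, and 4 of them with an estimated correlation too. These were G2 and M phase genes, higher in 22 of 22 (adjusted p = 3.06e-62, and 0.00605 with an estimated correlation), glucocorticoid targets, higher in 17 of 19 and lower in 1 (1.81e-26 and 0.00486), cAMP targets, higher in 11 of 18 and lower in 5 (2.48e-10 and 0.00432), and matrix genes, lower in 18 of 21 and higher in 3 (8.8e-10 and 0.0468). The 5 lower cAMP targets were 3 without 0 h replicate 2. Interferon genes were lower in 21 of 21 (1.71e-24, but adjusted p = 0.0719 with an estimated correlation). These counts were the same adjusted over the list alone.

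The differences of DHA and of DM from EtOH overlapped. Of the genes higher with DHA, 415 were also higher with DM, where 211 would be found if the calls were independent (n1 × n2 / N), and of the genes lower with DHA, 378 were also lower with DM, where 157 would be found. Opposite calls were made for 166 genes higher with DHA and lower with DM, and for 43 of the reverse kind. Both are fewer than independent calls would give. Without EtOH replicate 1 the counts were 251 and 238 in the same direction and 110 and 28 in opposite directions, and without DHA replicate 1 they were 218, 232, 108 and 28. Without EtOH replicate 3 the genes higher in both numbered 264, and without DHA replicate 2 the 43 became 81. Across genes, which are not independent replicates, the log2 fold changes had r = 0.280 and rho = 0.285. Both comparisons share the 3 EtOH libraries. In 20 simulated draws without any difference between groups, sharing them gave a mean r of 0.498, and 0.1 genes called higher and 0 called lower in both. With no gene changed in the draws, hardly any call was possible, so these counts cannot show what sharing adds to the overlap. The r of the draws is that of noise alone, so the r of the data cannot be judged by it. The covariance was 0.0939 in the data and 0.0254 in the draws, a difference of 0.0686. The 3 EtOH libraries cannot be divided into separate control groups of at least 2, so part of the excess may come from the shared controls. Against DM minus 0 h, which shares no library with DHA minus EtOH, r was 0.242 and rho 0.230 (r = 0.0499 without a filter, 0.375 at a minimum of 5 CPM and 0.0148 over kallisto transcripts), with 433 genes higher in both (212 if independent) and 367 lower in both (158 if independent). These were 280 and 233 without EtOH replicate 1, and 246 and 225 without DHA replicate 1.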

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

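The test for immune cells, the counts of genes with opposite directions with a library left out, and the gene Ccnd1 were chosen only after the results were seen. A set of 209 genes was called in opposite directions by DHA and by DM, each against EtOH, and was also called between DHA and DM. Of these, 166 were higher with DHA and lower with DM, and 43 were the reverse. Both counts lie under what independent calls (n1 × n2 / N) would give, since 65.5% of tested genes were changed for DM against EtOH. Of the 1129 genes changed for DHA against EtOH, 76.3% had the same sign for DM against EtOH. The 209 became 138 without EtOH replicate 1 and 136 without DHA replicate 1, with 110 and 28 genes in the first case and 108 and 28 in the second, and without DHA replicate 2 the 43 became 81. Fabp4 had log2 fold changes of 2.09 with DHA and −0.76 with DM, Acta2 of 0.65 and −4.08, and Ccnd1, a cyclin, of 0.44 and −2.04. Abca1 had −0.74 with DHA and 1.51 with DM. The matrix and contractile list differed between the groups by a mean log2 fold change of 1.07 (DHA minus DM), and camera called that difference (adjusted p = 2.83e-06), although not with an estimated correlation (adjusted p = 0.163). No biological explanation of these differences was tested, and the components of the media are not given.

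The interferon genes that were lower with DHA than with EtOH were weighed first. If 1 library carried the difference, leaving it out would end most calls, but at least 20 of the 21 genes were called lower with any of the 6 libraries left out. Immune cells in the EtOH cultures would bring leukocyte transcripts, but Ptprc, Laptm5, Itgam and Adgre1 together had 1 count over the 3 EtOH libraries. Both values argue against these explanations. A response of the cells to the DHA cocktail may explain the pattern, but it stays open as untested, as does any difference between cultures that follows the groups.

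The PPAR target genes that were higher and the cholesterol genes that were lower with DHA were weighed next. After each library was thinned to the smallest total, 41 of the 41 called genes of both lists were still called in their direction, which argues against unequal depth. Removing the trend of the fold changes on a proxy of gene length, the ratio of counts to the authors' FPKM, left 100.1% of the difference between the lists' means, but this trend was at most 0.06 in size, so removing it decides nothing. In 1000 draws of other genes of matched proxy, a check chosen afterwards, sets of the same sizes differed in the direction of the lists by at most 21.4% of that difference, which argues against gene length as read by the proxy. An effect of the DHA cocktail on fatty acid and sterol genes could explain the pattern, as a hypothesis found in the same data, and other differences in handling between the groups stay open.

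The third pattern was the distance of DHA replicate 3 from its group in ribosomal share and in the chi-square between replicates. The chi-square covers ribosomal RNA genes too. By Spearman correlation of counts replicate 3 did not stand apart, at 0.9965 and 0.9963 with replicates 1 and 2, which had 0.9961 between them. On the second principal component replicate 2 lay farthest from the others, with 32.0, 23.4 and 29.5 in DHA replicates 1, 2 and 3. Genes are not independent replicates. Across 10259 of them, the deviation of DHA replicate 3 from the other DHA libraries correlated with the same proxy of gene length. The Spearman correlation was −0.394, and the largest among the other libraries at 24 h was 0.316 in size. With a proxy and not a measured transcript length, this is consistent with a difference in library preparation or RNA quality that depends on length, and its ribosomal share of 0.773% was the lowest of all libraries. The labels give no batch or RNA quality, so a cause in the culture stays open. Without this library, 874 genes were changed between DHA and EtOH, and camera called 14 lists.

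For the comparisons of 3 libraries with 3, there are 10 splits of the 6 libraries, too few for a share under 0.05. In each comparison, 1 of the 10 splits, the real one, gave as many changed genes as the real one. For DHA and EtOH the real split gave 1129 genes and the highest other split 60. At an unadjusted p under 0.05 the real split gave 2999 genes and the other splits at most 1577. For DM and EtOH the real split gave 9583 and the highest other 0 by edgeR, the only tool run on the splits, with at most 500 at an unadjusted p under 0.05. For DHA and DM the real split gave 9456 and the highest other 0, with at most 509 at an unadjusted p under 0.05. Every other split mixes libraries of both groups. A difference between the groups then widens the spread within each side, which leaves few calls. The low counts of the other splits therefore decide nothing.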

How the results depend on the processing

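Thinning, kallisto transcripts, group FPKM and the counts of list genes and of overlaps with each library left out were chosen only after the data had been seen. No named gene or list called in the main analysis had a mean or log2 fold change of the other sign under an alternative run on libraries, except the list of cAMP targets for DHA against 0 h, from 0.00 to −0.03 without DHA replicate 2. Group FPKM, which has no test, gave the sign of the log2 fold change of 1124 of the 1129 called genes for DHA against EtOH, 9410 of 9583 for DM against EtOH, 9242 of 9456 for DHA against DM, and 6205 of 6263, 6759 of 6849 and 9504 of 9650 for EtOH, DHA and DM against 0 h. The cause of the other signs was not tested. The list of CTCF, cohesin and EPAC was not called in the main fit, but camera called it without a filter. Its mean log2 fold change went from 0.06 to −0.11 (adjusted p = 0.0399) for DM against EtOH. For DHA against DM it went from −0.06 to 0.10 (adjusted p = 0.0411). The direction of these tests was not kept, so only the mean is known to change sign. Of the 13 genes of the list 12 passed the filter, so the means need not cover the same genes. The cause was not tested further. Counts of changed genes stayed within 1.5 times in all 6 comparisons under the alternatives run on genes, except DHA against EtOH, with 638 without DHA replicate 1 and 705 without EtOH replicate 1 (range with a library left out 638 to 1360, the highest without DHA replicate 2). Of 43245 kallisto transcripts, a different unit, 107 (0.247%) were changed for DHA against EtOH, 6809 for DM against EtOH, 6554 for DHA against DM, and 2983, 3513 and 7371 for EtOH, DHA and DM against 0 h. These counts are lower than those of genes, and the cause was not tested. Counts of genes that differed at least 2-fold moved by more than that at a minimum of 5 CPM, where fewer genes are tested, in all 6 comparisons. With an estimated correlation camera called 7 lists for DHA against EtOH, 3 for DM against EtOH, 1 for DHA against DM, 3 for EtOH, 8 for DHA and 4 for DM against 0 h. Fry, which tests a list without comparing it with other genes, called 21, 20, 21 and 20 for DM against EtOH, DHA against DM, EtOH against 0 h and DM against 0 h. With the most changed member of a list left out, a check chosen after the data had been seen, calls were lost for glucocorticoid targets (adjusted p = 0.566) and matrix genes (0.378) for DHA against EtOH, cholesterol genes (0.0723) for DHA against DM, cAMP targets (0.325), S-phase (0.115) and oxidative stress genes (0.0898) for EtOH against 0 h, stress response genes (0.159) for DHA against 0 h and adipocyte markers (0.0512) for DM against 0 h. For EtOH against 0 h the mean of the cAMP targets also changed sign, from 0.10 to −0.02 without Rgs2. Calls were gained for preadipocyte genes for DM against EtOH (0.0179), DHA against DM (0.0211) and DHA against 0 h (0.0294), glucocorticoid targets for DM against EtOH (0.0418) and stress response genes for EtOH against 0 h (0.00456). Without a filter, 11 lists were called for DM against EtOH. The cause of these differences in list calls was not tested. The correlation of DHA against EtOH with DM against EtOH was 0.392 without a filter, 0.357 at a minimum of 5 CPM, 0.415 over kallisto transcripts, and 0.220 to 0.316 with a library left out. With DM against 0 h it was 0.0499, 0.375, 0.0148 and 0.213 to 0.243, and 0.217 over group FPKM. The cause of these moves was not tested. Correlations of deviations from the group means lay between −0.15 and 0.07 for libraries of the same replicate number, and between −0.17 and 0.19 for different numbers. They show no pairing by number. With means of 2 or 3 libraries, they cannot exclude that a number marks a shared culture or day. With a replicate term 859 genes were changed for DHA against EtOH. Of 649 values of named genes, 45 had a call lost or gained under some alternative. With a library left out of the 0 h group, its lone library is assumed to vary like the other groups. A kallisto fit per gene was not run for lack of a map from transcripts to genes, nor a limma fit of FPKM, which has 1 value per group. After thinning to the smallest library, 1071 genes were changed for DHA against EtOH and 6111 for EtOH against 0 h. In data simulated at the depth, spread and number of these libraries, which were not varied, 78% of genes changed 1.5-fold were recovered for DHA against EtOH and 60% for EtOH against 0 h. Fewer genes were changed in those simulations than were called in the data.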

Other observations

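The test in this part was set before its own result was seen. Peg10 was not among the genes fixed beforehand, and was taken up after its rise had been seen. Peg10 lies beside Sgce, an imprinted neighbour on the opposite strand, and a rise of the whole locus might explain the rise of Peg10 with DHA. Sgce had a log2 fold change of −0.0147 (95% interval −0.10 to 0.07), which argues against that explanation. Pdk4, which also lies within 1000 kb, was called higher at 0.94, as in the list of PPAR targets, and the cause of the rise of Peg10 stays open.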
